A study of Homo sapiens with 60 samples.

How the data were processed

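RNA from Huh7 and PLC cells was measured on 60 Illumina bead arrays in 20 groups of 3, defined by the line, culture format, density, treatment and sphere generation given in the sample titles. Per the labels' protocols, biotinylated cRNA was made from total RNA. The growth and treatment protocols in the labels described mice, so doses, days in culture and passage were not given in the sources used here. Per the file headers, the non-normalized file held an intensity and a detection p-value per probe and array for 29377 probes, and the submitters' processing notes named GenomeStudio 2011.1, while any step between scanning and that deposited table was not given in the sources used here. The smallest deposited detection p-value above 0 was about 1 in 290. The deposited series matrix held the intensity values after quantile normalization without a log, with the same ranks on each array, and was used as an alternative only. Each sample column was matched to its group by the sample number in the labels, and 0 sample columns were left unused.

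Intensities were processed with neqc of limma 3.58.1 in R 4.3.3, with the data.table package at version 1.17.8. This step corrected the background with normexp, took the mean and SD of negative controls inferred from the detection p, added an offset of 16, normalized by quantiles over all 60 arrays and took log2. Probe accessions were matched to the reference table for 26524 probes, which changed 3745 symbols, and 2853 probes without a match kept the symbol in the file. The 18401 probes with a symbol and a detection p under 0.01 on at least 3 arrays were kept, and the probe with the highest mean stood for each of 13788 genes. Of all probes, 6916 were detected on every array.

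A limma model with 1 mean per group was fitted to all arrays (40 residual degrees of freedom), and 29 comparisons, differences of effects among them, were tested with moderated t-tests. The p-values were adjusted by Benjamini-Hochberg over genes within each comparison, genes were called at adjusted p under 0.05, and calls of at least 2-fold were counted too. Camera with a preset correlation of 0.01 tested 28 gene lists, adjusted over the lists within a comparison, with an estimated correlation and fry as alternatives. The lists covered DNA methylation machinery, cancer-testis and germline genes, imprinted genes, interferon response, antigen presentation, liver progenitor and cancer stem cell markers, pluripotency and self-renewal, hepatocyte differentiation, mesenchymal genes, epithelial genes, cell cycle, p53 targets and cell cycle inhibitors, hypoxia and glycolysis, and cholesterol and fatty acid synthesis. They further covered the unfolded protein and amino acid stress response, NRF2 and xenobiotic response, NF-kB and inflammatory genes, WNT, Notch and TGF-beta targets, pyrimidine salvage and deamination, metallothioneins, histone genes, ribosomal proteins, oxidative phosphorylation, collagens and matrix, and markers of fibroblasts, endothelial cells, blood cells and bile duct cells. The groups, 29 comparisons, lists, tests and most alternatives were chosen before the data were examined, whereas 4 comparisons, the fits without the failing array and those without the marker genes of the 12-array set were added after.

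Genes open to being named followed a fixed rule. In main comparisons these were DNMT1, the 6 largest increases and 6 largest decreases among called genes whose groups did not overlap and that were detected in the higher group, and up to 4 members of each list described. Further comparisons used 3 of each and up to 2 members, and genes without a symbol were passed over. Genes of the sex chromosomes that show the sex of a donor were not examined. Effects of comparisons without common arrays were compared by correlation across genes and by the overlap of calls, and those with common arrays against simulated data.

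The steps were run on simulated data with 200 of 13788 genes changed. Real genes correlate within lists (cell cycle 0.43), so the rates need not hold for them. At 1.5, 2 and 4-fold, 23 of 67, 51 of 67 and 66 of 66 changed genes were called for ZEB in high-density monolayers. These were 26, 60 and 66 for ZEB in high-density Huh7 spheres and 20, 59 and 66 for density in shDNMT1 cells. Format gave 25, 54 and 66. Unchanged genes were called 6, 7, 12 and 8 times, the shifted list in each and 0, 0, 2 and 0 other lists.

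Alternatives were normexp with an offset of 50, no background correction, median scaling, the series matrix, no detection filter (20566 genes), a filter at 6 arrays (12910 genes), every probe alone, a fit of only the groups compared, eBayes with trend and robust, array weights, a block for the replicate number and leaving out each array. Replicate numbers were checked by correlating deviations from group means. Arrays of different groups had a mean r of 0.008 with the same number and -0.004 with different numbers, and 11 of 190 pairs of groups exceeded 0.1, so the numbers were not taken as pairs, although 31 of 60 arrays (51.7%) had their best match in another group under the same number. A block for the chip was not run, since the sample columns name no chip.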

Results

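Gene expression was measured on 60 Illumina arrays of 2 human liver cancer cell lines, Huh7 and PLC, which fell into 20 groups of 3 arrays. Huh7 cells were sampled as monolayers and as spheres (free-floating cell clusters) and PLC cells as spheres, at low or high density and untreated or treated with zebularine (ZEB), a cytidine analogue that inhibits DNA methyltransferases. Low-density ZEB spheres of both lines were sampled in sphere generations 1, 3 and 4 (G1, G3 and G4), and Huh7 cells carrying a short hairpin RNA against the DNA methyltransferase DNMT1 (shDNMT1) at both densities in these generations. The series held no untreated low-density spheres, no Huh7 cells with a control hairpin and no PLC monolayers, and the labels did not give the culture format of the shDNMT1 cells. The total signal per array ran from 4298620 to 15703700 intensity units and the probes detected from 9524 to 15113. Nothing in the labels stated that the 3 arrays of a group came from separate cultures, so every p-value measured the spread between these samples, which may be technical. The arrays of a group are given as n = 3, and changes are on the log2 scale with the standard error (SE) of the limma model over 13788 genes. Where no array of a group detected a gene, its change is a lower bound, written as at least a value, against the lowest level among the probes detected on those arrays or the gene's own if higher.

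The arrays of a group resembled each other in 19 of the 20 groups, where each array correlated with its own group at a mean r across genes of 0.964 to 0.992. In untreated high-density PLC spheres, replicate 2 correlated with its group at 0.771, and 917 genes, 20 of the 58 ribosomal protein genes among them, lay over 8-fold lower on it than on both other arrays. That array is called the failing array, and counts without it are given beside the comparisons it moved. A set of 12 Huh7 arrays also stood apart, namely the G1 spheres (low-density ZEB, high-density untreated, high-density ZEB) and the low-density untreated monolayers. On 70 genes they all lay above or all below the other 48 arrays, against at most 43 genes for any other of the 4845 choices of 4 groups. NOMO3, of an endoplasmic reticulum membrane complex, reached at most 4.62 in the set and at least 6.04 outside it. For RNA28SN5, a ribosomal RNA gene, these were 9.81 and 11.0. For a probe matched to CDC14B they were 9.08 and 10.1, but another CDC14B probe did not follow. Among the Huh7 arrays alone, 75 genes lay lower and 43 higher on each of the 12 arrays than on any of the other 33 (called its marker genes from here on), and comparisons across that line are named as crossing the 12-array set.

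**Figure D1:**
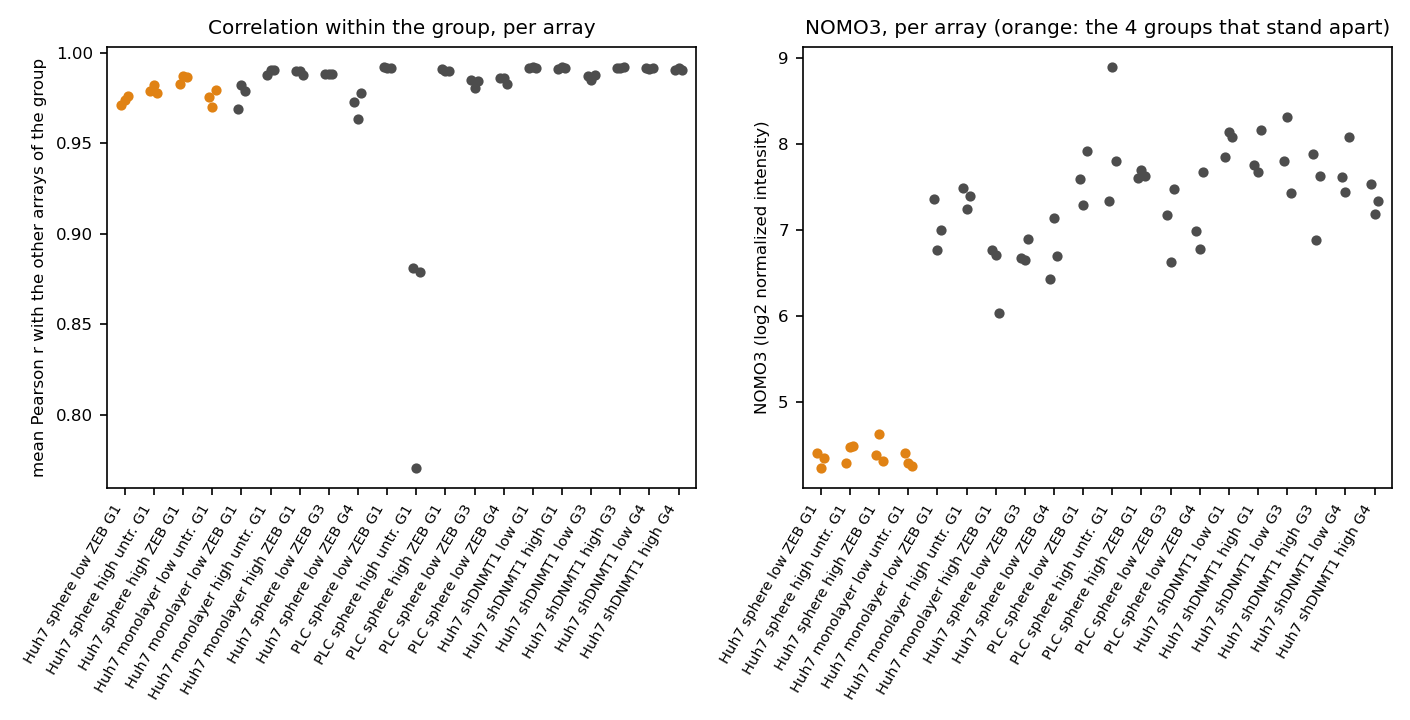
The first panel plots the mean correlation (r across genes) of each array with its own group and the second the log2 level of NOMO3 on each array, by group, with 1 point per array. The failing array lies at r 0.771, and the 12 arrays of the set lie at or below 4.62 for NOMO3 while all others lie at or above 6.04.

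DNMT1, the maintenance DNA methyltransferase and target of the hairpin, was read by 1 probe and detected in all groups. In Huh7 cells without the hairpin the group means ran from 11.72 ± 0.11 (SD, n = 3) in untreated high-density spheres to 12.39 ± 0.11 in ZEB spheres of G3. Monolayers lay at 12.26 ± 0.18 (high density, untreated), 12.15 ± 0.08 (high density, ZEB), 12.25 ± 0.12 (low density, untreated) and 12.13 ± 0.62 (low density, ZEB). The remaining sphere groups lay at 11.78 ± 0.33 (low-density ZEB, G1), 12.12 ± 0.20 (high-density ZEB) and 12.11 ± 0.41 (low-density ZEB, G4). The shDNMT1 groups lay lower, at 11.39 ± 0.08, 11.01 ± 0.16 and 10.99 ± 0.24 for high density in G1, G3 and G4 and at 10.90 ± 0.28, 10.89 ± 0.22 and 11.11 ± 0.07 for low density. PLC spheres lay between 11.11 ± 0.18 and 11.57 ± 0.11. Of the 18 shDNMT1 arrays, 16 lay below each of the 27 other Huh7 arrays, and the group means averaged 11.05 against 12.10. DNMT1 was lower in high-density shDNMT1 cells of G1 than in high-density untreated monolayers by -0.87 ± 0.22 (limma adjusted p = 0.0035). Against high-density untreated spheres the difference was -0.33 ± 0.22 (adjusted p = 0.27). No ZEB comparison in G1 passed the test for DNMT1.

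**Figure D2:**
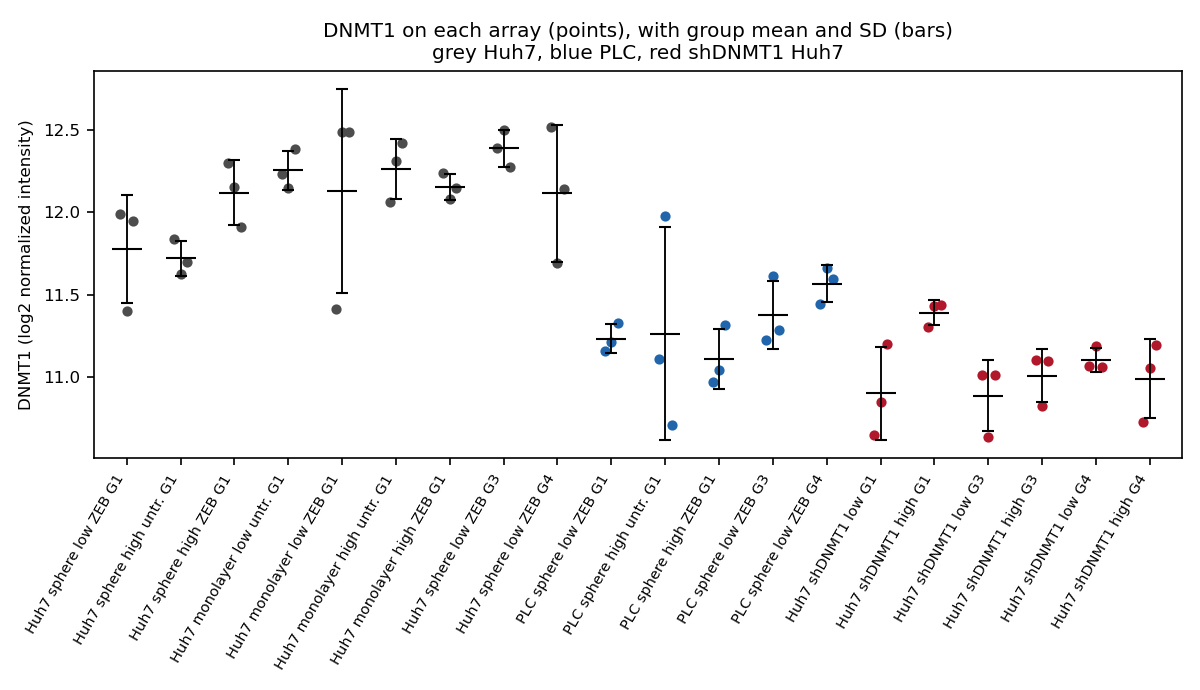
The log2 level of DNMT1 is plotted for each array (points) with the mean and SD of its group, by group. The shDNMT1 arrays lie at or below 11.44 and the other Huh7 arrays at or above 11.40.

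ZEB was first compared with no treatment in dense Huh7 monolayers. CXCR4, a chemokine receptor of migrating cells, rose by 3.36 ± 0.31 (n = 3 per group, limma adjusted p = 9.3e-11), followed by BDNF, a neurotrophin, at 1.93 ± 0.25, and NEXN, an actin-binding protein, at 1.92 ± 0.22. STC2, a secreted glycoprotein induced by stress of the endoplasmic reticulum, fell by 3.23 ± 0.39 (adjusted p = 9.3e-08). DDIT4, a stress-induced inhibitor of mTOR signalling, fell by 2.71 ± 0.61, GPAM, an enzyme of triglyceride synthesis, by 2.42 ± 0.20, SERPINA3, an acute-phase protease inhibitor, by 2.40 ± 0.27, and ASNS, asparagine synthetase, by 2.21 ± 0.20. Of the 38 genes of the unfolded protein and amino acid stress response, 14 fell, 0 rose and 24 did not pass (23 fell when adjusted over the list alone). The list was lower by the camera test (adjusted p = 3.9e-14, and adjusted p = 0.00016 with an estimated correlation).

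Genes of cholesterol and fatty acid synthesis fell with them, 11 of 34 (20 when adjusted over the list alone), with LSS, lanosterol synthase, at -1.34 ± 0.24 (camera adjusted p = 9.9e-12, and adjusted p = 0.0013 with an estimated correlation). Of 49 hepatocyte differentiation genes 9 fell and 1 rose (12 and 1 adjusted over the list alone). Among them ASS1 of the urea cycle fell by 2.06 ± 0.63 and AHSG, a plasma protein, by 1.99 ± 0.36 (camera adjusted p = 0.00015, and adjusted p = 0.0094 with an estimated correlation). Metal-binding metallothioneins rose, 4 of 8 (5 adjusted over the list alone), with MT1E at 1.29 ± 0.25 (camera adjusted p = 4.6e-05, and adjusted p = 0.014 with an estimated correlation). Cell cycle genes were called higher (4 of 58 rose, none fell, 4 adjusted over the list alone; camera adjusted p = 0.0017) and collagens and matrix genes lower (5 fell and 1 rose of 25; camera adjusted p = 0.021). Both calls were lost, with adjusted p = 0.72 and adjusted p = 0.053 with an estimated correlation.

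Gene classes often silenced by DNA methylation did not move as lists in these dense monolayers. Of 33 cancer-testis and germline genes only LIN28B passed, at 0.51 ± 0.15 (camera adjusted p = 0.81), and of 23 imprinted genes PHLDA2 rose by 0.94 ± 0.29 while GRB10 and SLC67A1 fell by 0.73 ± 0.22 (0.20 higher on another probe) and 0.76 ± 0.20 (camera adjusted p = 0.64). Of 36 interferon response genes 1 fell, IFIT1, by at least 0.41 (camera adjusted p = 0.62). No gene of the DNA methylation machinery was called by limma among 14, the largest value being 0.52 ± 0.36 for UHRF1 (camera adjusted p = 0.69). In all, limma called 1235 genes, 572 higher and 663 lower, 292 of them by at least 2-fold. The count was 778 and 768 without untreated replicates 1 and 3, 813 and 748 without ZEB replicates 1 and 3, and 1929 without the failing array, which entered only through the pooled variance.

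With ZEB in low-density Huh7 monolayers, CXCR4 rose by 2.80 ± 0.31 (n = 3 per group, limma adjusted p = 4.9e-09). DUSP4, a MAP kinase phosphatase, rose by at least 2.26 (adjusted p = 3.4e-12). MEST, an imprinted gene, rose by at least 1.38, TGFB2, a growth factor, by 1.66 ± 0.25, and TEX15, a germline gene, by 1.71 ± 0.28. DCK, deoxycytidine kinase, rose by 2.52 ± 0.25 and RRM2, of ribonucleotide reductase, by 2.60 ± 0.48. All SEs here pool all groups, and whether single arrays drive these rises was not tested. LSR, a lipoprotein receptor, fell by 2.01 ± 0.29, RELB, a subunit of NF-kB, by 1.34 ± 0.25, and CDKN2A, a cell cycle inhibitor, by 0.95 ± 0.18 (0.32 higher on another probe). The comparison crossed the 12-array set, to which the untreated arrays belonged, and 113 of the called genes were among its marker genes. RNA28SN5 and CDC14B, with the largest increases at 4.66 ± 0.52 and 3.95 ± 0.48 (-0.96 on another CDC14B probe), were among them, and so were MEST and LSR.

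No list moved in the low-density monolayers by camera. Of the 33 cancer-testis and germline genes 2 rose and 1 fell, of the 23 imprinted genes 2 rose and 1 fell, and of the 36 interferon response genes 1 rose and 1 fell (camera adjusted p = 0.93 for each; adjusted over the list alone 2 and 0, 2 and 1, and 0 and 0). Of 38 stress response genes 5 fell, CEBPB, a transcription factor of that response, by 0.85 ± 0.21 and ASNS by 0.62 ± 0.20 (camera adjusted p = 0.57), and of 34 cholesterol and fatty acid genes 5 fell and 2 rose (camera adjusted p = 0.93). In all, limma called 2125 genes, 1045 higher and 1080 lower, 598 of them by at least 2-fold, and 1983 on leaving out the marker genes from testing, but 52 in a fit of only the groups compared and 5164 with array weights. The count was 743 without untreated replicate 2, 1297 without ZEB replicate 2 and 1204 without ZEB replicate 3. Across genes, the ZEB effect at low density correlated with that at high density at r 0.22, where 275 genes were called the same way (103 higher and 172 lower, against 43.4 and 51.9 by chance) and 40 in opposite ways. Genes are not independent replicates in these correlations.

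Density itself was compared in Huh7 monolayers. In untreated cells at low density metallothioneins rose, 8 of 8 (8 adjusted over the list alone), with MT1E at 3.59 ± 0.25 and MT2A at 3.53 ± 0.34 (n = 3 per group, limma adjusted p = 4.4e-15 and 5.7e-11), and LTB, a lymphotoxin, rose by at least 3.36. SCNN1A, a sodium channel subunit, fell by 4.79 ± 0.34 and STC2 by 4.41 ± 0.39. Cholesterol and fatty acid genes fell, 23 of 34 (23 adjusted over the list alone), INSIG1, a regulator of sterol synthesis, by 3.29 ± 0.63. Stress response genes fell, 19 of 38 against 4 that rose (21 and 4 adjusted over the list alone), and 10 WNT, Notch and TGF-beta targets fell while 2 rose of 24 (11 and 3 adjusted over the list alone). Camera gave adjusted p = 2.8e-11, 1.5e-11, 9.6e-06 and 0.023 for the metallothioneins, the cholesterol, the stress and the WNT list. With an estimated correlation these were adjusted p = 0.00025, 0.0012, 0.026 and 0.033 (the last 0.054 without the failing array). The comparison crossed the 12-array set, with 98.3% of its marker genes called, RNA28SN5 among them at -4.87 ± 0.52. Limma called 5006 genes, 2596 higher and 2410 lower, and 4873 without these genes. With median scaling the call was of 6895 genes, 4619 higher and 2276 lower.

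Between the ZEB-treated monolayers, which both lay outside the 12-array set, low density went with higher UBD, a ubiquitin-like modifier induced by inflammation, at 3.52 ± 0.31 (limma adjusted p = 5.7e-11, n = 3 per group), LTB by at least 1.97 and AKR1B10, an aldo-keto reductase, at 2.06 ± 0.36. HAMP, the iron hormone hepcidin, fell by 4.19 ± 0.39 (adjusted p = 2.5e-10) and SCNN1A by 3.22 ± 0.34. Again metallothioneins rose, 7 of 8 (7 adjusted over the list alone), cholesterol and fatty acid genes fell, 14 of 34 (16 adjusted over the list alone), and WNT, Notch and TGF-beta targets fell, 4 of 24 with 1 higher (4 and 1 adjusted over the list alone), SP5 by at least 1.21. Camera gave adjusted p = 8e-12, 1.7e-08 and 0.0071, and with an estimated correlation adjusted p = 0.00013, 0.0099 and 0.02. NRF2 and xenobiotic genes rose, 8 of 30 (camera adjusted p = 0.002), and NF-kB genes rose, 6 of 33 with 1 lower (camera adjusted p = 0.0067), though not with an estimated correlation (adjusted p = 0.18 and 0.23). Limma called 1463 genes, 711 higher and 752 lower, of which 1034 were called the same way as in untreated monolayers (r across genes 0.61). The count was 727 without low-density replicate 1, and 922 and 685 without high-density replicates 2 and 3.

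Relative to high density, the ZEB effect at low density was more positive for the stress genes CTH, a cysteine-forming enzyme, by at least 1.97 and STC2 by 2.40 ± 0.54 (n = 3 per group, limma adjusted p = 0.0005 and 0.0041). It was more positive for SPP1, osteopontin, by 1.95 ± 0.36 and for ALDH1A1, a retinal dehydrogenase, by 1.18 ± 0.30, both progenitor markers. In untreated low-density cells CTH was undetected and STC2 already lower, leaving less room for a fall. MT1E differed by -2.02 ± 0.35 and S100A4, a calcium-binding protein of motile cells, by -2.63 ± 0.40. Higher calls numbered 7 of 38 stress genes, 4 of 34 cholesterol genes and 3 of 18 progenitor markers, and lower calls 4 of 8 metallothioneins (8, 6, 3 and 6 adjusted over the list alone). The camera adjusted p = 2.2e-05 held for the first, the second and the last of these and 0.0064 for the progenitor markers, with adjusted p = 0.034, 0.043 (0.097 without the failing array), 0.034 and 0.034 with an estimated correlation. Hepatocyte genes were also called, 3 of 49 higher (adjusted p = 0.022, and 0.096 with an estimated correlation). With median scaling, which put the median of all genes at -0.25 (from -0.055), the medians of the progenitor and hepatocyte lists turned from 0.27 and 0.19 to -0.02 and -0.15. Limma called 939 genes, 530 higher and 409 lower, and median scaling 1392, 552 higher and 840 lower. This comparison crossed the 12-array set, with 73 of its marker genes called. The count was 846 without these genes, 416 without low-density untreated replicate 2 and 1451 without the failing array.

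**Figure D3:**
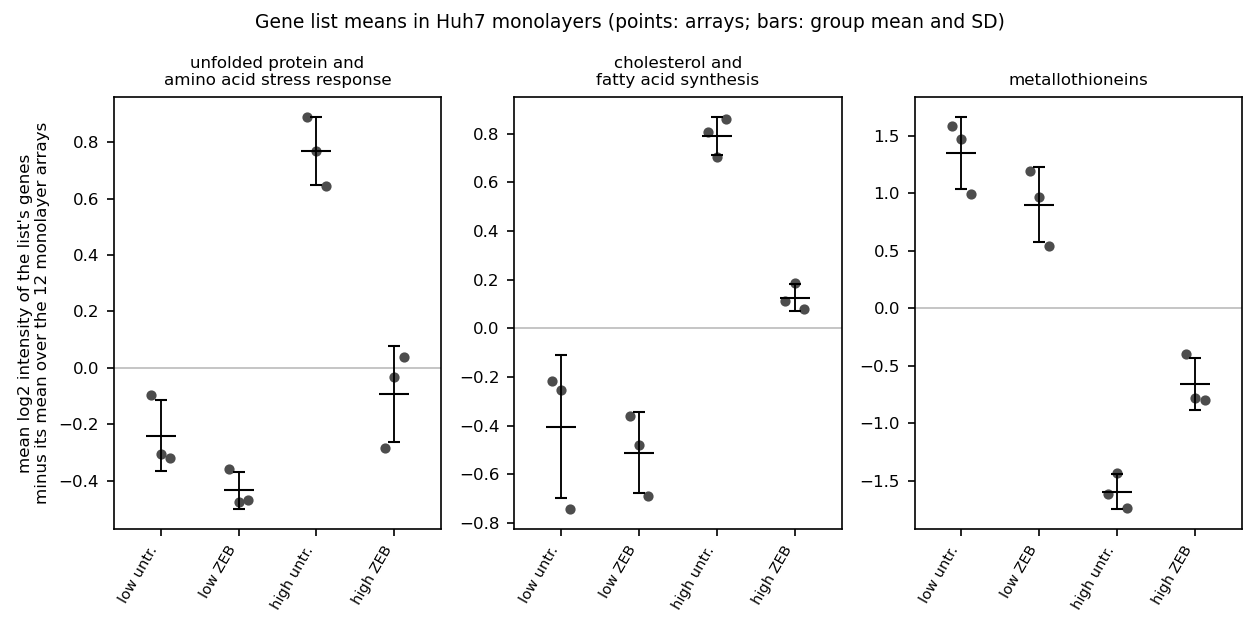
The mean log2 level of the members of 3 gene lists, each gene centred on its mean over the 12 monolayer arrays, is plotted for each array (points) with the mean and SD of its group (n = 3). High-density untreated monolayers lie highest for the stress response list (0.77 ± 0.12) and the cholesterol list (0.79 ± 0.08) and lowest for metallothioneins (-1.60 ± 0.15).

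Few genes passed the test for ZEB in high-density Huh7 spheres. GAD1, which makes the neurotransmitter GABA, rose by at least 0.40 (another probe -0.012, n = 3 per group, limma adjusted p = 0.0031), DNAJC11, a mitochondrial chaperone, by at least 0.30, MARS2, a mitochondrial tRNA synthetase, by 1.09 ± 0.21 and NEXN by 1.06 ± 0.22. APOB, the main protein of secreted lipoproteins, rose by 1.35 ± 0.30 (adjusted p = 0.037). FBXL16 fell by 1.02 ± 0.22 and PRSS22 by 0.95 ± 0.21. Of 58 cell cycle genes none passed by limma, with CENPF, a kinetochore protein, at 0.93 ± 0.32, but their median lay at 0.46 and camera called the list higher (adjusted p = 8.1e-10, but 0.42 with an estimated correlation). None of 41 hypoxia and glycolysis genes passed, with ENO2, an enolase, at -1.73 ± 0.54 and the median at -0.45 (camera adjusted p = 3.3e-08), and none of 34 cholesterol genes, with the median at -0.28 (camera adjusted p = 0.0013), both also with adjusted p = 0.42 with an estimated correlation. Adjusted over the list alone these counts were 0, 1 lower and 0.

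The classes tied to DNA methylation again showed no list call in these spheres. Among 33 cancer-testis genes, 23 imprinted genes and 14 genes of the methylation machinery limma called 0, the largest values being 0.93 ± 0.29 for PHLDA2 and 0.95 ± 0.36 for UHRF1 in the latter 2 (camera adjusted p = 0.65, 0.78 and 0.20). In all, limma called 20 genes, 16 higher and 4 lower, 11 by at least 2-fold, but 0 with an offset of 50, with median scaling or in a fit of only the groups compared, and 1785 had an unadjusted p under 0.05. Of the 20, 4 were also called the same way in dense monolayers (3 higher and 1 lower, against 0.66 and 0.19 by chance, r across genes 0.26). The count rested on single arrays: 350 and 1 without untreated replicates 1 and 3, 1 and 52 without ZEB replicates 1 and 3, and 77 without the failing array.

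Low-density ZEB spheres of Huh7 were compared with the only untreated spheres, those at high density, a contrast that mixes ZEB with density. IGF2, an imprinted growth factor, fell by 2.44 ± 0.44 (n = 3 per group, limma adjusted p = 0.0018), NPDC1 by 1.76 ± 0.30 and C1R, a complement protease, by 1.33 ± 0.26. NETO2, an accessory protein of glutamate receptors, rose by 1.44 ± 0.24 (adjusted p = 0.0012), MAD2L1, of the spindle checkpoint, by 1.43 ± 0.34, SLC17A8 by 1.42 ± 0.28, and TRIM32 by 1.11 ± 0.19. Of 58 cell cycle genes MAD2L1 alone rose (1 adjusted over the list alone), with the list median at 0.31, and none of 41 hypoxia and glycolysis genes passed by limma (0 adjusted over the list alone), with SLC2A3, a glucose transporter, at -1.38 ± 0.54. Both lists had camera adjusted p = 0.0031 and adjusted p = 0.64 with an estimated correlation. Limma called 62 genes, 32 higher and 30 lower, and 1886 had an unadjusted p under 0.05. With median scaling 24 genes were called, 4 higher and 20 lower, and 0 in a fit of only the groups compared. The count was 125, 403 and 11 without ZEB replicates 1, 2 and 3, 551 and 7 without untreated replicates 1 and 3, and 151 without the failing array.

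Density was compared in ZEB spheres of Huh7. At low density ATG4B, a protease of autophagy, fell by 3.26 ± 0.56 (n = 3 per group, limma adjusted p = 0.0024), PSMC4 by 3.13 ± 0.70, FADS2, a fatty acid desaturase, by 3.00 ± 0.52, PKP3, a protein of desmosomes, by 2.91 ± 0.53, ALYREF by 2.91 ± 0.58 and KRT18, an epithelial keratin, by 2.83 ± 0.66. MSI1, an RNA-binding protein of neural stem cells, rose by at least 0.52 and PRKCI by 0.78 ± 0.16. No cell cycle gene of 58 passed by limma (0 adjusted over the list alone), with RRM2 at -1.62 ± 0.48 and the median at -0.14, while camera called the list lower (adjusted p = 0.041, and adjusted p = 0.89 with an estimated correlation). Limma called 37 genes, 5 higher and 32 lower (0 in a fit of only the groups compared), and 1255 had an unadjusted p under 0.05. The count was 280, 8 and 0 without low-density replicates 1, 2 and 3, 11 and 9 without high-density replicates 1 and 2, and 88 without the failing array.

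ZEB in high-density PLC spheres was compared with untreated arrays, among them the failing array. With it, RPL38, a ribosomal protein, lay higher under ZEB by 3.16 ± 0.88 (n = 3 per group, limma adjusted p = 0.043), and so did YBX1, a nucleic acid-binding protein, by 2.97 ± 0.79 (another probe 0.15) and MCM7, a replication helicase subunit, by 2.80 ± 0.72. MAPK13, a stress kinase, lay lower by -1.19 ± 0.25 and LPIN1, a phosphatidate phosphatase, by -1.16 ± 0.27. Of 58 ribosomal protein genes 21 were called higher, of 30 NRF2 and xenobiotic genes 9 higher and 1 lower, and of 58 cell cycle genes 6 higher (22 higher and 1 lower, 13 and 5, and 6 and 0 adjusted over the list alone). Camera adjusted p = 1.8e-05, 0.0008 and 6.5e-05 became adjusted p = 0.097, 0.32 and 0.81 with an estimated correlation. Limma called 873 genes, 629 higher and 244 lower, 915 (567 and 348) with another background correction (normexp with an offset) 424 (356 and 68) with median scaling and 0 in a fit of only the groups compared. Without the failing array limma called 0 genes, with 580 at an unadjusted p under 0.05, and RPL38 lay at 0.21 and MAPK13 at -0.96. Camera then called 7 lists, and 1 with an estimated correlation. The count was 2429 and 2222 without untreated replicates 1 and 3 and 0, 11 and 2 without ZEB replicates 1, 2 and 3.

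Low-density ZEB spheres of PLC were compared with the same untreated high-density spheres, a contrast that mixes ZEB with density. TFF1, a secreted trefoil peptide of mucous epithelia, fell by 1.87 ± 0.38 (n = 3 per group, limma adjusted p = 0.0081) and MAPK13 by 1.75 ± 0.25 (adjusted p = 7.1e-05), and both passed without the failing array as well, at -2.03 and -1.52 (adjusted p = 0.031 and 0.0053). FBLN2, an extracellular matrix protein, FOXC2, a transcription factor of mesenchyme, and LPIN1 fell by 1.51 ± 0.28, 1.36 ± 0.25 and 1.23 ± 0.27 with the failing array, and lay at -0.96, -1.03 and -0.89 without it (adjusted p = 0.16, 0.14 and 0.36). The largest increases, among them YBX1 at 3.00 ± 0.79 (another probe -0.10) and MCM7 at 2.90 ± 0.72, came with the failing array. Camera called ribosomal proteins (21 of 58 higher), cell cycle (7 of 58), NRF2 and xenobiotic genes (11 of 30, and 2 lower) and oxidative phosphorylation (12 of 45) higher, at adjusted p = 2.8e-06, 3.9e-07, 0.023 and 0.023. Adjusted over the list alone 22, 7, 14 and 13 were higher and 5 NRF2 genes lower. All 4 calls were lost with an estimated correlation (adjusted p = 0.067, 0.51, 0.37 and 0.3). The oxidative phosphorylation median was -0.02, against its test (0.13 with median scaling). Without the failing array camera called 8 lists, 1 with that correlation. Limma called 1236 genes, 770 higher and 466 lower, but 11 without the failing array, 10 of them shared, and 0 in a fit of only the groups compared. It called 2712 and 2650 without untreated replicates 1 and 3, and 107, 38 and 76 without ZEB replicates 1, 2 and 3.

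Between low- and high-density ZEB spheres of PLC, a contrast free of the failing array, limma called 1 gene, ALPL, a tissue alkaline phosphatase, which rose by at least 0.47 (n = 3 per group, adjusted p = 0.032). At an unadjusted p under 0.05 there were 290 genes. No interferon gene of 36, no antigen presentation gene of 19 and no mesenchymal gene of 22 passed by limma, with IFI27 at -1.04 ± 0.34, HLA-DPA1 at -0.92 ± 0.29 and COL6A1 at -0.71 ± 0.24, and 0 passed in each when adjusted over the list alone. Their medians of -0.11, -0.12 and -0.11 gave camera adjusted p = 0.034, 0.034 and 0.047, and adjusted p = 0.36, 0.32 and 0.32 with an estimated correlation. The cell cycle, stress response and matrix lists, with medians of 0.10, -0.11 and -0.13 and 0 members called by limma (0 adjusted over the list alone), had camera adjusted p = 0.047 each and adjusted p = 0.81, 0.36 and 0.32 with an estimated correlation. The count was 4 and 0 without low-density replicates 1 and 3 and 0 and 3 without high-density replicates 2 and 3.

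The lines were compared for these effects in spheres. For ZEB at high density the difference of PLC from Huh7 had the largest values at IGFBP1, a hypoxia-induced binding protein of insulin-like growth factors, at 3.75 ± 1.11, and at RPL18, a ribosomal protein, at 3.20 ± 1.37 (n = 3 per group, limma adjusted p = 0.29 for each). Limma called 0 genes, with 2116 at an unadjusted p under 0.05. None of 58 ribosomal protein genes and none of 41 hypoxia genes passed (0 adjusted over the list alone), while camera gave adjusted p = 1.3e-05 and 0.0032 and, with an estimated correlation, adjusted p = 0.087 and 0.65. Without PLC untreated replicates 1 and 3 limma called 1300 and 1321 genes, without Huh7 untreated replicates 1 and 2 it called 5 and 1, without Huh7 ZEB replicate 1 and PLC ZEB replicate 3 it called 1 each, and without the failing array 0. For low against high density of ZEB spheres limma called 0 genes, with 777 at an unadjusted p under 0.05, and RRM2 differed by 1.99 ± 0.68 (adjusted p = 0.72). The cell cycle list (0 of 58 called, 0 adjusted over the list alone) had camera adjusted p = 0.0013 and adjusted p = 0.68 with an estimated correlation. Without Huh7 low-density replicate 1 the count was 67. The ZEB effects at high density correlated between the lines at r 0.11 across genes (0.27 without the failing array), and the contrasts of low-density ZEB with high-density untreated spheres at 0.083 (0.18).

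Format was compared in high-density untreated Huh7 cells. In spheres the trefoil peptides of mucous and biliary epithelia rose, TFF2 by 5.52 ± 0.33, TFF1 by 5.15 ± 0.38 and TFF3 by 3.70 ± 0.33 (n = 3 per group, limma adjusted p = 1.7e-17, 2.2e-14 and 3.9e-12). CA9, a carbonic anhydrase induced by hypoxia, rose by at least 4.13, ANGPTL4, a lipase inhibitor induced by fasting and hypoxia, by 3.48 ± 0.35, and ENO2 by 3.41 ± 0.54. Of 41 hypoxia and glycolysis genes 22 rose and 0 fell (24 adjusted over the list alone). Of 58 cell cycle genes 34 fell and 0 rose (38 adjusted over the list alone), RRM2 by 2.33 ± 0.48, KIF11, a mitotic kinesin, by 1.77 ± 0.36 and CDK1, the mitotic kinase, by 1.70 ± 0.31. ENPP2, which makes lysophosphatidic acid, fell by 3.09 ± 0.19, CYP1A1, a xenobiotic-metabolising enzyme, by 3.10 ± 0.36, and EFHD1, a mitochondrial calcium-binding protein, by 3.38 ± 0.33. Camera adjusted p = 4.7e-08 for the hypoxia list and 6.9e-10 for the cell cycle list became adjusted p = 0.2 and 0.26 with an estimated correlation.

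Some immune and mesenchymal genes rose in these spheres as well. Interferon response genes rose, 13 of 36 with 2 lower, led by IFITM3, an antiviral membrane protein, at 3.16 ± 0.30, and antigen presentation genes rose, 7 of 19, with PSMB10, an immunoproteasome subunit, at 1.71 ± 0.18. Mesenchymal genes rose, 9 of 22 with 1 lower, S100A4 by 2.33 ± 0.29 and AXL, a receptor kinase, by at least 1.86, and NF-kB genes rose, 9 of 33, LTB by at least 2.38. Stress response genes fell, 14 of 38 with 3 higher, ASNS by 1.97 ± 0.20. Adjusted over the list alone the counts were 16 and 3, 8 and 0, 9 and 1, 9 and 0, and 3 higher and 15 lower. Camera adjusted p = 0.0014, 0.0046, 0.0041, 0.016 and 0.0041 for these 5 lists became adjusted p = 0.15, 0.13, 0.13, 0.26 and 0.13 with an estimated correlation. Limma called 4269 genes, 2042 higher and 2227 lower, 1447 by at least 2-fold. The comparison crossed the 12-array set, to which the spheres belonged, with 115 of its marker genes called and 4137 calls without them. With median scaling, which put the median of all genes at 0.31 (from 0.023), limma called 6677 genes, 4899 higher and 1778 lower.

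Low-density ZEB Huh7 cells were compared by format too. TFF2 rose in spheres by 5.57 ± 0.33, BGN, a matrix proteoglycan, by at least 4.26 and CA9 by at least 3.30 (n = 3 per group, limma adjusted p = 3.5e-17, 7.7e-12 and 4.4e-06). Of 34 cholesterol and fatty acid genes 21 rose (25 and 1 lower adjusted over the list alone), MVD, which makes isopentenyl diphosphate, by 2.65 ± 0.28, and all 8 metallothioneins fell (8 adjusted over the list alone), MT1G by 2.45 ± 0.28. Camera gave adjusted p = 2.1e-12 and 3.7e-08, and adjusted p = 0.0015 and 0.0017 with an estimated correlation. Cell cycle genes fell, 29 of 58, hypoxia genes rose, 20 of 41, and interferon genes rose, 15 of 36 with 2 lower (34, 21, and 15 and 2 adjusted over the list alone), with camera adjusted p = 1.1e-10, 2.4e-07 and 0.0013 and adjusted p = 0.22 each with an estimated correlation. Limma called 3840 genes, 2142 higher and 1698 lower, of which 1998 were called the same way as in high-density untreated cells (1072 higher and 926 lower, against 317.2 and 274.3 by chance) and 95 in opposite ways, with r 0.64 across genes. This comparison crossed the 12-array set as well, with 110 of its marker genes called and 3703 calls without them.

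To compare formats on 1 side of the 12-array set, untreated high-density spheres were set against untreated low-density monolayers inside it and low-density ZEB spheres of G3 against low-density ZEB monolayers outside it, a choice made after the values were seen. These contrasts mix format with density in the first case and with generation in the second. BGN rose by at least 4.627 and 4.198, TFF2 by 5.11 ± 0.33 and 4.34 ± 0.33, CA9 by at least 3.46 and 2.93, and IFITM3 by 3.15 ± 0.30 and 3.41 ± 0.30. ENPP2 fell by 2.98 ± 0.19 and 2.83 ± 0.19, GPX2, a glutathione peroxidase, by 2.66 ± 0.45 and 3.32 ± 0.45, and FGF19, a hormone of bile acid control, by 1.66 ± 0.19 and 2.21 ± 0.19 (the highest limma adjusted p of these was 2.2e-05, n = 3 per group). Limma called 4155 and 4238 genes, of which 851 were higher in both and 732 lower in both (322.7 and 312.2 by chance) and 189 moved in opposite ways, with r 0.49 across genes. These named genes were chosen after the values were seen.

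**Figure D4:**
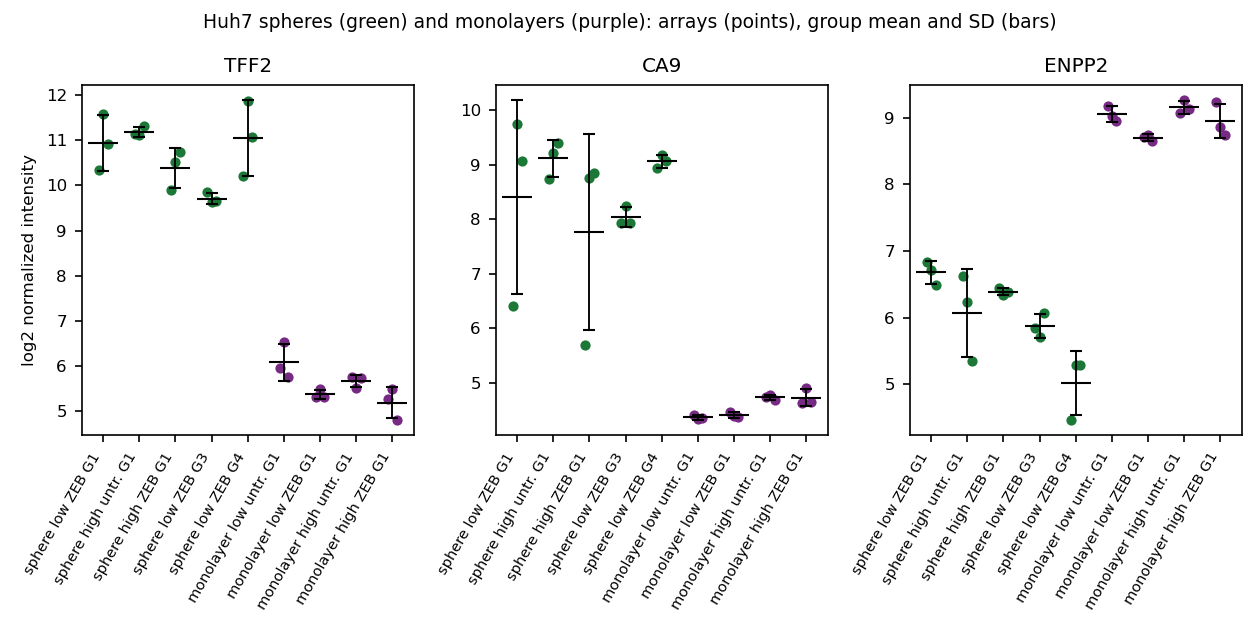
The log2 level of TFF2, CA9 and ENPP2 is plotted for each array (points) with the mean and SD of its group (n = 3), for the Huh7 groups without the hairpin. TFF2 lies at 9.71 or above in the means of the Huh7 sphere groups and at 6.08 or below in those of the monolayers, and CA9 varies by up to 1.80 (SD) within the Huh7 sphere groups of G1.

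The high-density ZEB effect was compared between Huh7 spheres and monolayers. The effect in spheres was more negative for CXCR4 by -3.51 ± 0.43 (n = 3 per group, limma adjusted p = 1.3e-06), for CD3D, a T-cell receptor subunit, by -1.98 ± 0.27 and for CRABP2, a carrier of retinoic acid, by -2.01 ± 0.46. It was more positive for STC2 by 2.54 ± 0.54, ASNS by 2.04 ± 0.28, AKR1C2 by 2.31 ± 0.39 and COL18A1, a basement membrane collagen, by 1.58 ± 0.31 (another probe -0.12). Of 38 stress response genes 4 were called higher (8 and 1 lower adjusted over the list alone) and of 8 metallothioneins 1 lower (4 adjusted over the list alone), with camera adjusted p = 2.9e-09 and 0.00014 and adjusted p = 0.0038 and 0.038 with an estimated correlation (the latter 0.083 without the failing array). Camera also called the hypoxia list lower (1 of 41 called, adjusted p = 0.00016) and the cholesterol, hepatocyte, NRF2 and matrix lists higher (2 of 34, 2 of 49, 4 of 30 and 3 of 25 called, adjusted p = 0.00046, 0.0069, 0.0021 and 0.022). These 5 calls were lost (adjusted p = 0.4, 0.12, 0.08, 0.14 and 0.08 with an estimated correlation; 1, 2, 9, 5 and 7 genes called adjusted over the list alone). Limma called 211 genes, 151 higher and 60 lower, and with median scaling 338, 113 higher and 225 lower. Each effect was taken within 1 side of the 12-array set. The count was 95 without untreated sphere replicate 3, 327 without untreated sphere replicate 1, 124 without ZEB sphere replicate 2, at most 132 without any 1 monolayer array or ZEB sphere replicate 1, and 420 without the failing array.

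Low-density ZEB Huh7 spheres were followed from G1 to G3 and G4. From G1 to G3, SAA2, an acute-phase serum amyloid, rose by at least 3.12 and CXCL6, a neutrophil chemokine, by 2.92 ± 0.21 (n = 3 per group, limma adjusted p = 1.7e-17 and 5.8e-15), within 12 of 33 NF-kB genes that rose and 2 that fell (12 and 2 adjusted over the list alone). TMEM45B fell by 3.33 ± 0.24, MMP15 by 3.03 ± 0.32 and TRIM71, a stem cell ubiquitin ligase, by at least 1.87. Of 49 hepatocyte genes 10 fell (10 adjusted over the list alone), ASGR2 of the asialoglycoprotein receptor by 2.09 ± 0.21 (1.28 higher on another probe), of 14 bile duct markers 11 fell (11 and 1 higher adjusted over the list alone), and of 8 metallothioneins 4 rose (6 adjusted over the list alone). Camera adjusted p = 7.3e-05, 0.015, 0.00063 and 0.00058 for these 4 lists became adjusted p = 0.06, 0.1, 0.06 and 0.06 with an estimated correlation. DNMT1 rose by 0.61 ± 0.22 (adjusted p = 0.038), a call lost in a fit of only the groups compared. Limma called 3595 genes, 1705 higher and 1890 lower, with 113 marker genes of the 12-array set, which G1 belonged to and G3 did not, and 3452 without them. Its r across genes with ZEB in low-density monolayers, which also crossed the set, was 0.41.

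From G1 to G4, TRIM71 fell by at least 1.76 (n = 3 per group, limma adjusted p = 5.2e-11), XAGE2B, a cancer-testis antigen, by 2.38 ± 0.22 and LIMK1, a kinase of actin turnover, by at least 1.29. FOXM1, a transcription factor of mitosis, fell by 2.22 ± 0.38 and CDC25B, a cell cycle phosphatase, by 1.28 ± 0.23. Of 58 cell cycle genes 11 fell and 0 rose (10 adjusted over the list alone), and of 45 oxidative phosphorylation genes 13 fell and 6 rose (16 and 6 adjusted over the list alone), COX7B of cytochrome oxidase by 0.83 ± 0.20. Both had camera adjusted p = 0.039 and adjusted p = 0.99 and 0.54 with an estimated correlation. KRT18 rose by 3.85 ± 0.66, and ADAM9, a membrane protease, by at least 2.76, RNA28SN5 by 5.88 ± 0.52 and CDC14B by 5.67 ± 0.48 (another probe -0.53), 3 marker genes of the 12-array set. Limma called 3059 genes, 1454 higher and 1605 lower, 96.6% of the marker genes of the set, which the comparison crossed, among them, 2907 without these and 737 in a fit of only the groups compared. The G3 and G4 effects correlated at r 0.75 across genes, with 1903 called the same way. Simulated data with no change gave 0.50 (covariance 0.0363 against 0.244). Both effects use the G1 arrays of the set, whose offset the simulation lacked, so it cannot test agreement.

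G4 was also compared with G3, both outside the 12-array set, a comparison added after the values were seen. SAA2 fell by at least 2.83 (n = 3 per group, limma adjusted p = 7.3e-19), OLR1, a scavenger receptor for oxidised lipoproteins, by 3.78 ± 0.22 and FEZ1, a neuronal transport protein, by at least 1.76. PPARGC1A, a coactivator of mitochondrial and gluconeogenic genes, rose by at least 1.97. Of 33 NF-kB genes 10 fell and 1 rose (12 and 1 adjusted over the list alone), of 8 metallothioneins 5 fell (8 adjusted over the list alone), and of 49 hepatocyte genes 9 rose (14 adjusted over the list alone), ARG1 of the urea cycle by 1.43 ± 0.39. By camera they had adjusted p = 7.2e-13, 7.2e-13 and 4.1e-06, and adjusted p = 0.00062, 8e-05 and 0.0015 with an estimated correlation. Limma called 746 genes, 427 higher and 319 lower.

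In PLC the same generations were compared, from G1 to G4. LEPR, the leptin receptor, rose by 3.52 ± 0.33 (n = 3 per group, limma adjusted p = 9.8e-11), BEX1, a neuronal adaptor, by 3.33 ± 0.42, GAS2 by 2.91 ± 0.24 and ALB, albumin, by 2.35 ± 0.45. MT1X, a metallothionein, fell by 3.83 ± 0.86, GAL3ST1 by 3.30 ± 0.37 and CA9 by 2.84 ± 0.64. Of 41 hypoxia and glycolysis genes 11 fell and 0 rose (13 adjusted over the list alone), NDRG1, a stress-induced growth regulator, by 2.31 ± 0.62 and ENO2 by 2.03 ± 0.54 (camera adjusted p = 1.7e-12, and adjusted p = 0.17 with an estimated correlation). Of 14 bile duct markers KRT19, a ductal keratin, fell by 2.16 ± 0.20, SOX9, a ductal transcription factor, by 2.00 ± 0.27 and ANXA4 by 1.29 ± 0.25, while the chloride channel CFTR rose by 1.07 ± 0.25 (3 and 1 adjusted over the list alone). That list was lower with camera adjusted p = 6e-05 and adjusted p = 0.044 with an estimated correlation, but 0.073 without the failing array.

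Cell cycle genes had a median of 0.51 in the same comparison, with MCM5, a replication helicase subunit, called at 1.04 ± 0.31 and 57 of 58 not passing (0 adjusted over the list alone; camera adjusted p = 5.2e-11, and adjusted p = 0.2 with an estimated correlation). NF-kB genes fell, 3 of 33, CXCL8 by 2.19 ± 0.32, and interferon genes fell, 4 of 36 with 2 higher, BST2 by 1.71 ± 0.27 (3, and 8 with 2 higher, adjusted over the list alone). These lists had camera adjusted p = 0.043 and 0.0052 and, with an estimated correlation, adjusted p = 0.28 and 0.2. Limma called 607 genes, 211 higher and 396 lower, and with median scaling 751, 165 higher and 586 lower. The count was 344 without G1 replicate 3, 252 without G4 replicate 2 and 1018 without the failing array.

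From G1 to G3 of PLC, LEPR rose by 3.82 ± 0.33, BEX1 by 3.65 ± 0.42 and GAS2 by 3.06 ± 0.24 (n = 3 per group, limma adjusted p = 2.2e-11, 3.2e-08 and 1.1e-12), and GAL3ST1 fell by 3.28 ± 0.37, SOX9 by 2.19 ± 0.27, KRT19 by 2.02 ± 0.20 and CXCL8, a neutrophil chemokine, by 2.03 ± 0.32. Hypoxia genes fell, 9 of 41 (11 and 1 higher adjusted over the list alone), and bile duct markers fell, 3 of 14 with 1 higher (5 and 2 adjusted over the list alone), with camera adjusted p = 1.8e-09 and 0.00014 and adjusted p = 0.21 and 0.066 with an estimated correlation. Limma called 517 genes, 170 higher and 347 lower, 299 without G1 replicate 3, 282 without G3 replicate 2 and 796 without the failing array. The G3 and G4 effects of PLC shared their G1 arrays and correlated at r 0.81 across genes (0.50 in simulated data with no change, with a covariance of 0.116 against 0.0368), with 353 genes called the same way in both.

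The G4 effect was compared between the lines. Relative to Huh7, the effect in PLC was more positive for BEX1 by 4.05 ± 0.60, LEPR by 3.17 ± 0.47, DDC, which decarboxylates aromatic amino acids, by 3.37 ± 0.58 and FOXM1 by 2.99 ± 0.53 (n = 3 per group, limma adjusted p = 5.2e-06, 4.9e-06, 5.5e-05 and 0.0001). It was more negative for CA12, a carbonic anhydrase, by -3.41 ± 0.39 and for CA9 by -3.49 ± 0.91. Of 58 cell cycle genes 14 were called higher (20 adjusted over the list alone) and of 41 hypoxia genes 9 lower and 1 higher (15 and 1), at camera adjusted p = 2.1e-08 and 2.1e-05, each with adjusted p = 0.54 with an estimated correlation. Limma called 2203 genes, 1174 higher and 1029 lower, and with median scaling 2226, 833 higher and 1393 lower. The Huh7 side crossed the 12-array set, with 99 of its marker genes called and 2069 calls without them. The G4 effects of the lines had r -0.088 across genes, with 53 genes called the same way and 90 in opposite ways.

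In shDNMT1 Huh7 cells, low and high density were compared in each generation. In G1, RRAGD, a GTPase of amino acid sensing, rose at low density by 1.90 ± 0.30, CD44, a hyaluronan receptor used as a stem cell marker, by 1.88 ± 0.31, FBXO32 by 1.86 ± 0.28 and PLA1A by 1.73 ± 0.28 (n = 3 per group, limma adjusted p = 0.00028, 0.00061, 0.00017 and 0.0003). SLC1A3, a glutamate transporter, fell by 0.93 ± 0.21. Of 38 stress response genes 4 rose (10 and 1 lower adjusted over the list alone), CTH by 1.53 ± 0.36, MTHFD2 of mitochondrial folate metabolism by 0.97 ± 0.17 and ASNS by 0.96 ± 0.20. Of 36 interferon genes IFIT2 rose by 1.43 ± 0.28 (7 adjusted over the list alone), and of 30 NRF2 genes TXNRD1, thioredoxin reductase, and HMOX1, heme oxygenase, rose by 1.13 ± 0.23 and 1.02 ± 0.20 (4 adjusted over the list alone). The camera values were adjusted p = 3.6e-07, 3.6e-07 and 3e-06 and, with an estimated correlation, adjusted p = 0.024, 0.041 and 0.041, all lost without the failing array (adjusted p = 0.052, 0.065 and 0.052) and by fry (adjusted p = 0.093, 0.093 and 0.36). None of 58 cell cycle genes passed by limma (0 adjusted over the list alone), with the median at -0.34, camera adjusted p = 3.1e-07 and adjusted p = 0.41 with an estimated correlation. Limma called 40 genes, 38 higher and 2 lower, and 801 had an unadjusted p under 0.05. The count was 9 and 11 without low-density replicates 1 and 2 and 11, 16 and 21 without high-density replicates 1, 2 and 3.

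In G3 limma called 14 genes, 3 higher and 11 lower (0 in a fit of only the groups compared). TRIM50 fell at low density by 1.43 ± 0.18 (n = 3 per group, limma adjusted p = 4.7e-06) and OSGIN1 by 1.44 ± 0.31, and SAA1 rose by 1.08 ± 0.22. The count was 3 and 5 without low-density replicates 2 and 3, 6 and 2 without high-density replicates 2 and 3, and 9 without low-density replicate 1. In G4 limma called 0 genes, with 336 at an unadjusted p under 0.05. There the oxidative phosphorylation list had a median of -0.16 (0 of 45 called, 0 adjusted over the list alone), camera adjusted p = 0.0002 and adjusted p = 0.02 with an estimated correlation. Collagens and matrix genes had a median of 0.13, with COL4A1, a basement membrane collagen, at 0.52 ± 0.22 (0 of 25 called, 0 adjusted over the list alone), camera adjusted p = 0.013 and adjusted p = 0.04 with an estimated correlation. Without the failing array that correlation gave adjusted p = 0.06 for both, and fry 0.27.

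From G1 to G4, TMPRSS2, a serine protease of epithelial surfaces, rose in low- and high-density shDNMT1 cells by 2.06 ± 0.21 and 2.41 ± 0.21, MMP7, matrilysin, by 1.88 ± 0.24 and 2.12 ± 0.24, and TDO2, which degrades tryptophan, by 1.60 ± 0.25 and 2.23 ± 0.25 (n = 3 per group, the highest limma adjusted p was 0.00011). At low density COL6A1, a collagen, rose by at least 1.40, while STC2 fell by 2.08 ± 0.39, MTHFD2 by 1.24 ± 0.17 and ASNS by 1.17 ± 0.20, all within 3 of 38 stress response genes that fell (9 and 1 higher adjusted over the list alone; camera adjusted p = 4.5e-05, and adjusted p = 0.09 with an estimated correlation). At high density LGALS3BP, a secreted glycoprotein, rose by 1.86 ± 0.36 and IFIT2 by 1.49 ± 0.28, within 3 of 36 interferon genes (10 adjusted over the list alone; camera adjusted p = 8e-05, and adjusted p = 0.12 with an estimated correlation), and LCN2, an iron-binding acute-phase protein, by 1.37 ± 0.32. Limma called 56 genes at low density (34 higher, 22 lower) and 127 at high density (94 higher, 33 lower), 28 of them the same way (27 higher, against 0.23 by chance) and 0 in opposite ways, with r 0.46 across genes.

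Single arrays moved these counts. At low density the count was 36 each without G1 replicates 1 and 2, and at high density 78, 63 and 64 without G1 replicates 1, 2 and 3 and 59 and 76 without G4 replicates 1 and 2. Without the failing array they were 138 and 204. The difference of the generation effects between the densities was called by limma for 1 gene, SULT2A1, a steroid sulfotransferase, at -1.84 ± 0.34 (n = 3 per group, adjusted p = 0.04), with 431 at an unadjusted p under 0.05. The count was 0 without any of G1 replicates 1 and 2 and G4 replicates 1 and 2 of either density or low-density G4 replicate 3, and 2 without low-density G1 replicate 3.

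Finally, high-density shDNMT1 cells of G1 were compared with high-density untreated Huh7 cells, without a control hairpin and with the format of the former unknown. Against monolayers, NPY, a neuropeptide, rose by at least 4.39, AMPH, a protein of endocytosis detected on 1 monolayer array, by 4.17 ± 0.27 and CXCL6 by 3.80 ± 0.21 (n = 3 per group, limma adjusted p = 2.3e-22, 2.3e-16 and 5.2e-19). LGALS14, a galectin detected on 1 shDNMT1 array, fell by 4.99 ± 0.37, EFHD1 by 3.92 ± 0.33 and APOA1, the main protein of high-density lipoprotein, by 2.98 ± 0.58. Of 33 NF-kB genes 16 rose and 1 fell (18 and 1 adjusted over the list alone), of 8 metallothioneins 7 rose (8), of 38 stress genes 15 fell and 2 rose (17 and 3), and of 25 collagens and matrix genes 9 fell and 2 rose (9 and 2), COL4A1 by 1.62 ± 0.22. Camera gave adjusted p = 3.1e-10, 5e-09, 0.00012 and 0.016 and, with an estimated correlation, adjusted p = 0.0023, 0.0014, 0.048 and 0.048, the last 2 lost without the failing array (adjusted p = 0.057 each). Of 11 blood cell markers 3 rose, CD68 by 3.08 ± 0.26 and LYZ by 2.64 ± 0.37 among them (camera adjusted p = 0.062). Of 33 cancer-testis genes MAGEA6 rose by 1.08 ± 0.22 and TEX15 fell by 1.17 ± 0.28, 1 and 2 being called higher and lower (1 and 1 adjusted over the list alone, camera adjusted p = 0.76), and of 23 imprinted genes H19 rose by 2.14 ± 0.62, with 2 higher and 2 lower (2 and 2 adjusted over the list alone, camera adjusted p = 0.72). Limma called 2727 genes, 1348 higher and 1379 lower.

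Against high-density untreated spheres, shDNMT1 cells had lower PNCK, a calmodulin kinase, by at least 5.56, lower ENO2 by at least 3.87 and lower CA9 by at least 4.09, and higher CXCL6 by 3.36 ± 0.21 and AKR1B1, aldose reductase, by 2.09 ± 0.18 (n = 3 per group, the highest limma adjusted p was 3.2e-07). Hypoxia genes fell, 20 of 41 (20 adjusted over the list alone), cell cycle genes rose, 21 of 58 with 1 lower (21 and 1), and NF-kB genes rose, 12 of 33 with 4 lower (12 and 5), at camera adjusted p = 1.5e-05, 0.00084 and 0.016, lost with an estimated correlation (adjusted p = 0.35, 0.5 and 0.35). With median scaling, which put the median of all genes at -0.32, the NF-kB median turned from 0.35 to -0.01. Limma called 4879 genes, 2500 higher and 2379 lower, and with median scaling 6752, 2023 higher and 4729 lower. The comparison crossed the 12-array set, with all of its marker genes called and 4747 calls without them.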

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

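The comparisons with other splits of the arrays or permuted residuals were planned before the data were examined, and the tests of the 3 patterns below were chosen after the results were seen. The difference of the ZEB effect between low- and high-density monolayers drew attention because effects differed between groups. It called 939 genes against at most 815 in the permutations (the real value was reached in 1 of 100, itself included). By the same criterion the difference of the ZEB effect between Huh7 spheres and monolayers called 211 genes (at most 2 otherwise, 1 of 100). The difference of the G4 effect between the lines called 2203 (at most 1088 otherwise, 1 of 100). The difference of the G4 effect between densities of shDNMT1 cells called 1 (at most 1 otherwise, 2 of 100). For both differences between the lines at G1 the real count was 0 and 100 of 100 permutations reached it, with up to 1960 and 10 calls.

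The 6 arrays of a pair of groups allow 10 splits, too few for a share under 0.05. In monolayers the real split called 2125, 1235, 5006 and 1463 genes for ZEB at low density, ZEB at high density, density untreated and density with ZEB, and the highest other split 1650, 1, 73 and 8 (1 of 10 each). In Huh7 spheres ZEB at high density called 20 against 12 (1 of 10). For low-density ZEB against high-density untreated Huh7 spheres, 62 genes were called against up to 783 in another split, and 3 of 10 splits reached 62. For density in ZEB spheres these were 37, 173 and 3 of 10, and for density in PLC spheres 1, 5 and 3 of 10. In PLC spheres ZEB at high density called 873 against 726 and low-density ZEB against high-density untreated 1236 against 6 (1 of 10 each). Format called 4269 against 1 (untreated) and 3840 against 2168 (ZEB), Huh7 G3 3595 against 182, G4 3059 against 1439, PLC G3 517 against 3 and G4 607 against 9 (1 of 10 each). In shDNMT1 cells density called 40, 14 and 0 in G1, G3 and G4 against 0 in any other split (1, 1 and 10 of 10), G4 against G1 56 and 127 against 0 and 1, and the comparisons with untreated spheres and monolayers 4879 and 2727 against 1 and 0 (1 of 10 each).

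The calls for ZEB in high-density PLC spheres were weighed first. Against 873 genes, 0 were called without the failing array, but 0, 11 and 2 without ZEB replicates 1, 2 and 3, so this count does not single it out. The size of the changes does, since 21.3% of the called genes kept at least 0.5 of their change without it and 100% without any of the other 5 arrays, and their median change of 1.49 became 0.21 against 1.46 to 2.19. If that array held the other cell line it would lie nearer Huh7 on most of 541 genes that separate the lines, but it lay nearer PLC on 89.3%. The failing array thus fits as the source of most of these changes, and why its signal was lost from highly expressed genes (median percentile 91.7) was not tested.

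The second pattern was the 12-array set, on whose 70 genes the 12 arrays lay apart from the other 48, but these groups were picked because they stood apart, so that count (43 for another choice) tests no cause. Other probes of its marker genes followed in 59.1%, against 60.0% for the genes that set shDNMT1 cells apart and 76.7% for those that separate the lines, and with a median change of 0.86 against 1.54 for the main probes, so whole transcripts and single probes both stay open. Lower signal stays open too, since the median of probes detected was 12568 in the set and 13923 outside and 75 marker genes lay lower, although 43 lay higher and 8 arrays outside had fewer probes detected than the set's median array. A shared handling of these cultures or RNAs may explain the set, but no label gives a date, so the comparisons across it cannot be separated from it.

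The third pattern was the lower stress and cholesterol genes in ZEB-treated dense monolayers. Both groups lay outside the 12-array set, and the stress list (adjusted p = 0.00016 with an estimated correlation) is the pattern itself, so it tests the set no further. If the treated cultures had merely been sparser, the ZEB effect on all other genes would follow the density effect with r of at least 0.3. Over the splits of the shared arrays r was 0.17 to 0.22 with low-density untreated cells, which belong to the 12-array set, and 0.42 to 0.48 with low-density ZEB cells, which share the treatment. A lower density in the treated cultures may therefore contribute, and these data do not decide it.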

How the results depend on the processing

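The alternatives were chosen before the data were examined, except the fits without the failing array for comparisons that do not hold it and those without the marker genes, chosen after the results were seen. Counts that moved over 1.5 times follow by setting, and all others moved less. The cause was not tested unless stated. No label separates the 12-array set from format, density or generation.

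For ZEB at high density in Huh7 spheres (20 genes) limma called 0 with an offset of 50 and 0 with median scaling, and 34 with no detection filter. For low-density ZEB against untreated (62) it called 38 with an offset of 50, 24 with median scaling and 184 with every probe alone, and for density with ZEB (37) 22 with that offset and 145 with every probe. In PLC spheres median scaling called 424 for ZEB at high density (873) and 677 for low-density ZEB against untreated (1236), and no filter 24 and 627. Density in PLC spheres (1) gave 0 with an offset of 50, no background correction, median scaling, the series matrix and the stricter filter, and the ZEB effect between lines (0) gave 1 with no filter, with the stricter filter and with every probe. Median scaling called 6677 for format of untreated cells and 338 for the ZEB effect between formats. For shDNMT1 density in G3 (14) 4 were called with no background correction, 6 with median scaling and 4 with the series matrix, and for G4 against G1 at low density (56) 85 with an offset of 50. The difference of that effect between densities (1) gave 2 with an offset of 50 and 0 with no background correction, median scaling, the series matrix, no filter and every probe. EBayes with trend and robust called 19 for ZEB in high-density PLC spheres.

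A fit of only the groups compared, with fewer arrays to estimate the spread, called 52 genes for ZEB in low-density monolayers, 2150 at high density, 641 for density with ZEB, 457 for the difference of ZEB effects and 0 in each of the 6 comparisons of G1 spheres within a line. It called 1790 for format with ZEB, 737 for Huh7 G4, 147 and 0 for shDNMT1 density in G1 and G3, 394 and 610 for shDNMT1 G4 at low and high density, 20 for their difference and 4531 for shDNMT1 cells against monolayers. Array weights, in the order of the report, called 5164 and 3394 for ZEB at low and high density, 3698 for density with ZEB, 3648 for their difference, 234, 346 and 204 in Huh7 spheres, 1, 85 and 15 in PLC spheres, 87 for density between lines, 5785 for format with ZEB, 1021 for the ZEB effect between formats, 1149 and 2238 for PLC G3 and G4 and 3733 for G4 between lines. In shDNMT1 cells they called 570 and 1.1e+02 for density in G1 and G3, 1099 and 1449 for G4, 71 for the difference and 5517 against monolayers. With the replicate block ZEB at high density in Huh7 spheres called 33 genes and the difference of shDNMT1 G4 effects 2. Of 130 list calls 29 stayed with an estimated correlation and fry called 150. Without the failing array 18 of the 29 stayed, and 2 in PLC spheres against untreated ones came up.

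Leaving out single arrays, the failing array included, gave ranges of 743 to 2868 and 748 to 1929 for ZEB in low- and high-density monolayers, 685 to 2125 for density with ZEB and 416 to 1451 for the difference. They were 1 to 350, 7 to 551 and 0 to 280 in Huh7 spheres, 0 to 2429, 11 to 2712 and 0 to 4 in PLC spheres, 0 to 1321 and 0 to 67 between the lines and 95 to 420 between formats. PLC G3 and G4 ranged from 282 to 796 and 252 to 1018, shDNMT1 density from 9 to 57 in G1 and 2 to 20 in G3, shDNMT1 G4 from 36 to 138 and 59 to 204 and its difference from 0 to 2.

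DNMT1 in untreated monolayers by density was 0.29 with median scaling, and the difference of ZEB effects on it -0.33 with median scaling and 0.288 with array weights, which gave 0.290 for density with ZEB. Format changed it by -0.54 in the fit of only these groups and without the failing array, and by -0.63 (untreated) and -0.65 (ZEB) with array weights, each passing. Array weights also called its density effect in shDNMT1 G1 (-0.50), whereas the G3 increase of 0.61 did not pass in the fit of only these groups. Without the failing array its ZEB effects in PLC spheres were 0.20 and 0.32 and their difference between lines -0.20. Apart from DNMT1, named genes, for which the failing array alone was left out, kept their sign in all settings run but every probe alone, where another probe of the gene turned. These were CDC14B (-0.96 for ZEB at low density, -0.53 for Huh7 G4), CDKN2A (0.32), GRB10 (0.20), GAD1 (-0.012), YBX1 (-0.10), COL18A1 (-0.12) and ASGR2 (1.28).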

Other observations

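Single genes of lists not called by camera changed with ZEB in high-density monolayers (values collected after the results were seen). Of 12 pluripotency genes MYCN, a proto-oncogene of embryonal tumours, fell by 1.68 ± 0.31 and DPPA2, a germ cell and early embryo gene, rose by 1.21 ± 0.19, 2 being higher and 1 lower (2 and 1 adjusted over the list alone; n = 3 per group, camera adjusted p = 0.62 for this list). Of 18 progenitor and stem cell markers 1 rose and 3 fell (1 and 3 adjusted over the list alone, camera adjusted p = 0.16), SPP1, osteopontin, by 1.37 ± 0.25 and GPC3, a cell surface proteoglycan, by 1.04 ± 0.20. NT5E, an ecto-nucleotidase, fell by 1.15 ± 0.20 among 28 genes of pyrimidine salvage and deamination, the pathway that handles ZEB (1 higher, 2 lower, 1 and 2 adjusted over the list alone, camera adjusted p = 0.69).

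Markers of other cell types were compared between formats of untreated high-density Huh7 cells. Of 11 blood cell markers CD3D, a T cell receptor chain, was higher in spheres by 3.85 ± 0.19, CD68, a macrophage lysosomal protein, by 3.44 ± 0.26 and LYZ, lysozyme, by 2.42 ± 0.37 (n = 3 per group, 3 adjusted over the list alone, camera adjusted p = 0.0046, and adjusted p = 0.0501 with an estimated correlation). Of 14 bile duct markers 5 were higher and 1 lower (5 and 1 adjusted over the list alone, camera adjusted p = 0.0059, and adjusted p = 0.13 with an estimated correlation), MUC1, a mucin, by 2.17 ± 0.27. Of 4 endothelial markers 3 were higher (3 adjusted over the list alone, camera adjusted p = 0.053), and of 8 fibroblast markers limma called 0 (0 adjusted over the list alone, camera adjusted p = 0.77). Of 28 pyrimidine salvage genes CDA, cytidine deaminase, was higher by at least 2.10 and DCK, deoxycytidine kinase, lower by -1.96 ± 0.25 (3 higher and 8 lower, 3 and 8 adjusted over the list alone, camera adjusted p = 0.34). MEST was lower by -2.97 ± 0.26 and H19 higher by 2.11 ± 0.62. Of 23 imprinted genes 4 were higher and 3 lower (4 and 5 adjusted over the list alone, camera adjusted p = 0.96). This comparison crossed the 12-array set, MEST is 1 of its marker genes, and 4137 genes were called without these.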
